A study of Mus musculus with 8 samples.

How the data were processed

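Gene expression was measured on 8 Affymetrix Mouse Genome 430 2.0 arrays hybridised with biotin-labelled RNA from dorsal skin of mouse embryos at embryonic day 18.5. These are single-colour arrays on which several short oligonucleotide probes together form a probe set. The groups were taken from the genotype labels: 4 arrays from embryos without the glucocorticoid receptor (GR-null) and 4 from wild-type embryos. Arrays are named by the numbers in their labels, which do not pair arrays across the groups. The labels call the embryos littermates but give no litter and do not state that each array came from a different embryo. The p-values therefore measure the spread between these samples.

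The deposited values are log2 expression values per probe set, made with RMA (robust multi-array average) per the submitters' processing notes. RMA subtracts background, equalises the distribution of intensities across arrays and summarises the probes of each set. Its version, the probe set definition used and any further filter are not given in the sources used here. RMA compresses differences near the background and near saturation, so fold changes of very dim or very bright transcripts are likely to be understated. Equal distributions across arrays also mean that a shift of most transcripts in one direction could not be seen. The array medians lay between 6.46 and 6.52. No detection calls or scan dates were used here. The precision of every value is limited by the number of arrays.

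The table held 45101 probe sets, of which 64 control probe sets were left out and 45037 were tested. By the platform annotation, 34945 of these carried 1 gene symbol, 932 carried several and 9160 had none listed. Probe sets with several symbols or none stayed out of gene counts. Of the 18194 genes with a probe set of their own, 18032 had identifiers found in the RefSeq gene table of assembly GRCm38.p6 and 162 kept the annotation's symbol. That table served for names and for the order of neighbouring genes, and no coordinates are given because no genome build is named for the array values.

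Differences were tested with limma 3.58.1 in R 4.3.3. A linear model with genotype as the single term was fitted to each probe set (lmFit), with the default variance prior over all probe sets (eBayes) and a two-sided test. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Log2 fold changes are GR-null minus wild-type. For genes, the same fit was read at the probe set with the highest mean over the 8 arrays among those annotated to that gene alone, and p-values were adjusted over the 18194 genes. On simulated arrays with the measured means and residual SDs, averaged over 10 runs with 200 of 18194 genes shifted, the gene-level fit recovered 44.0% of genes shifted by 0.5 log2, 86.9% of those shifted by 1 and 98.0% of those shifted by 2. On average 3.93% of its calls were false. The simulated noise was drawn independently for each probe set, so these rates leave out deviations that many genes share on an array.

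A set of 24 gene lists was fixed before the data were examined, together with the design, the rule for named genes and most of the other settings tried. The lists held glucocorticoid-induced genes, stages and functions of the epidermis, the hair follicle, the cell cycle, inflammation, wound response, dermal matrix, the circadian clock, steroid receptors, and markers of other cell types a skin sample can hold. Each list was tested against all other genes with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 24 lists. The counts of members past the threshold are given over all genes and adjusted over the list alone.

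Named genes were Nr3c1 with all its probe sets, then the 12 largest rises and the 12 largest falls among genes past the threshold whose GR-null values all lay on one side of all wild-type values. Clone-type symbols, immunoglobulin segments and sex-linked transcripts were passed over. In each list up to 4 members past the threshold with the largest change were named, and up to 8 in the list of glucocorticoid-induced genes. In a list with no such member, the 1 or 2 with the smallest p were named. A gene named outside this rule is said to have been chosen after its values were seen.

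The other settings fixed at that time were a further quantile normalization, a filter on dim probe sets, an intensity trend with a robust prior, array quality weights, leaving out each array in turn, the Y-linked level as a covariate, a block for label numbers below 10, a threshold of 0.01, a minimum of 1.5-fold, the mean of all probe sets of a gene, leaving out probe sets prone to cross-hybridisation (names ending in _x_at or _s_at), leaving out the 100 genes on either side of Nr3c1, camera with an estimated correlation, and limma's fry. Added after seeing the data were the mean of the skeletal muscle list as a covariate and a variance prior from 1 probe set per gene, the latter tried while the fit was being set up. Figures were drawn with matplotlib 3.10.9.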

Results

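Transcript levels in dorsal skin were compared between mouse embryos with and without the glucocorticoid receptor (GR), the steroid hormone-activated transcription factor encoded by Nr3c1. The question was which genes of the developing skin depend on the receptor shortly before birth, at embryonic day 18.5. The wild-type group held 4 arrays (label numbers 4, 6, 28 and 29) and the GR-null group held 4 (5, 17, 25 and 26). Across probe sets, which are not independent replicates, Pearson correlations lay between 0.987 and 0.993 within wild-type arrays, between 0.978 and 0.994 within GR-null arrays and between 0.974 and 0.988 across genotypes. The first principal component held 44.2% of the variance, with scores from -42.3 to -13.6 in wild-type arrays, above 0 and up to 61.3 in GR-null 5, 25 and 26, and -7.96 in GR-null 17. Xist, the RNA that coats the inactive X chromosome, read 13.22 log2 in wild-type 6 and 12.61 in GR-null 17, against 5.92 to 6.38 in the other 6 arrays. The Y-linked Eif2s3y read 3.43 and 3.31 in those 2 arrays and 8.83 to 9.51 in the others, so each genotype held 1 array of this kind.

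Nr3c1, the disrupted gene, was lower in every GR-null array than in every wild-type array at 3 of its 6 probe sets. At its second brightest probe set it read 9.93, 9.68, 9.74 and 9.92 log2 in wild-type 4, 6, 28 and 29, and 7.66, 8.01, 8.19 and 7.97 in GR-null 5, 17, 25 and 26. At the next probe set by brightness the values in the same order were 9.25, 8.88, 9.54 and 9.31, then 6.07, 7.05, 6.67 and 6.41. At the brightest they were 10.24, 10.32, 10.24 and 10.24, then 9.21, 9.24, 9.62 and 9.61. Nr3c1 fell by 1.86 ± 0.12 log2 (SE, n = 4 per group, adjusted p = 0.000831) at the second brightest probe set. It fell by 2.70 ± 0.21 (adjusted p = 0.00158) at the next, and at the brightest it fell by 0.84 ± 0.11 (adjusted p = 0.0133). The remaining probe sets, dimmer on average, had log2 fold changes of 0.27, 0.04 and 0.35 with adjusted p of 0.751, 0.888 and 0.196. Where each probe set lies relative to the disrupted part of the gene is not given in the sources used here, and a probe set outside that part does not check the genotype. With the mean of the skeletal muscle list as a covariate, the brightest kept its direction at -0.91 with adjusted p = 0.178.

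**Figure D1:**
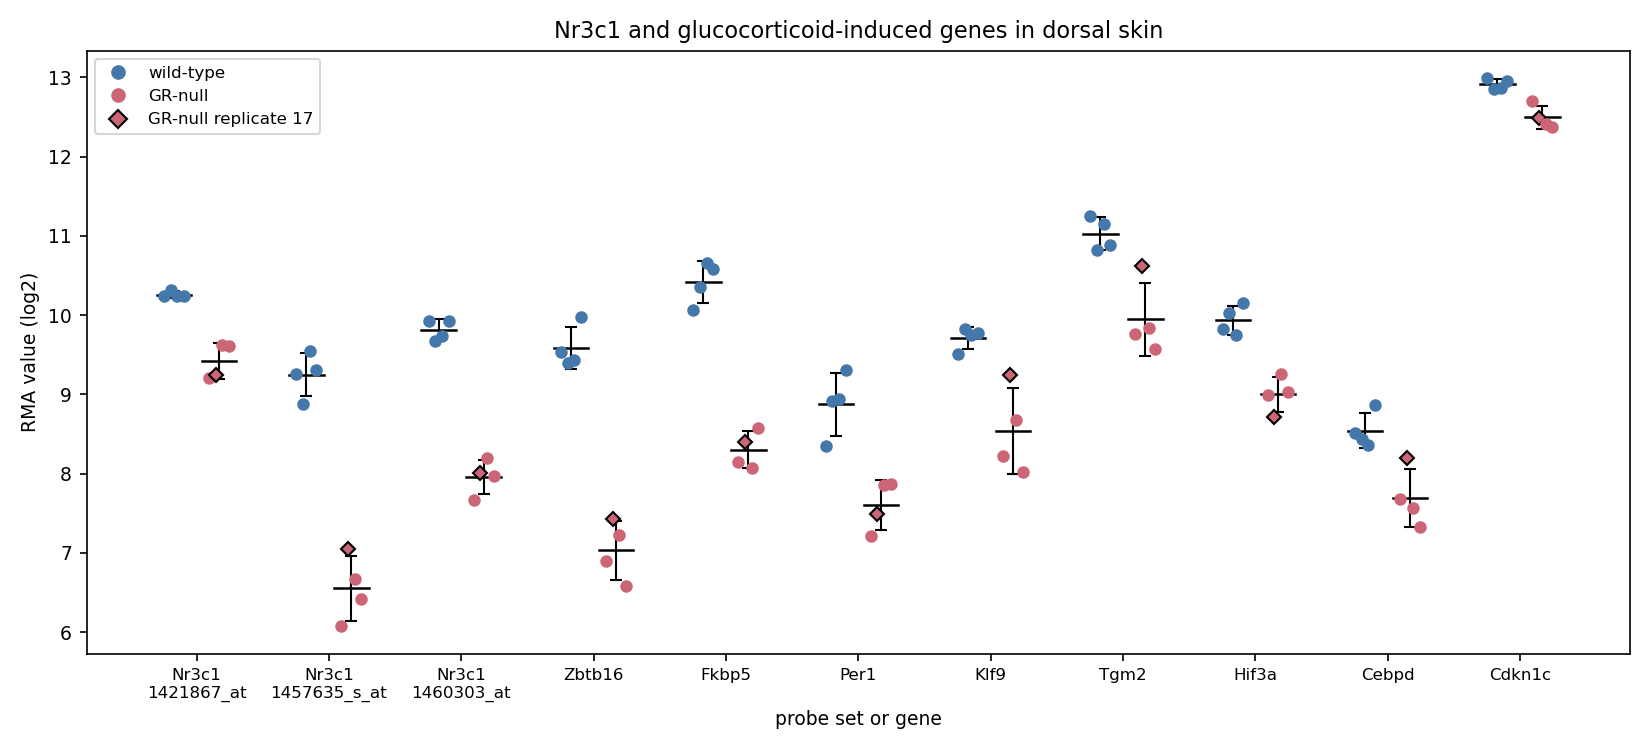
RMA values (log2) on each array for the 3 Nr3c1 probe sets past the threshold and for the 8 glucocorticoid-induced genes that fell, with 4 wild-type and 4 GR-null points each, the group mean as a horizontal line and the SD as an error bar. GR-null 17 is drawn as a diamond, and for Fkbp5 the GR-null values lie between 8.07 and 8.58 against 10.06 to 10.66 in wild-type.

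In GR-null skin the largest rise among genes past the threshold named by the fixed rule was that of the keratin Krt77, 23.0-fold, and the largest fall that of the cornified envelope precursor Sprr1b, 21.3-fold. At the gene level 539 of 18194 genes differed, 255 higher and 284 lower in GR-null skin. Changes of at least 2-fold comprised 24 rises and 76 falls. At the probe set level 1735 of 45037 differed, 1002 higher and 733 lower. The values of the groups did not overlap in 2365 of all 18194 genes tested, against 2.86% of genes by chance. They did not overlap in 536 of the 539, which selection by a small p all but requires. The mean of the skeletal muscle list was 10.74 ± 0.07 log2 (SD, n = 4) in wild-type and 10.22 ± 0.33 in GR-null arrays, and with it as a covariate 75 genes differed, 37 of them among the 539. That fit leans on GR-null 17, whose list mean was at the wild-type level. Without GR-null 17 the count rose to 1640 and included all 539. It was 295, 321, 142 and 104 without wild-type 4, 6, 28 and 29, and 186, 79 and 154 without GR-null 5, 25 and 26. The probe set count was 953, 2104, 203 and 215 without wild-type 4, 6, 28 and 29, and 468, 4866, 125 and 177 without GR-null 5, 17, 25 and 26. Of the 64 named genes past the threshold, 23 kept it in all 8 of these fits, and none changed direction in the alternatives in which it was read, 3 of which held 54, 60 and 63 of the 64. For all but Krt80 of the 64 the groups did not overlap, so leaving out 1 array could not have reversed them. Calls ended for 26, 21, 37 and 36 of them without wild-type 4, 6, 28 and 29, for 33, 40 and 30 without GR-null 5, 25 and 26, and for none without GR-null 17. With the muscle covariate 49 of the 64 calls ended and 15 were kept, and with the block for label numbers below 10, 14 ended. Of the 49 ended by the muscle covariate, 37 had a smaller fold with it, such as Elf5 at 2.26 log2 (adjusted p = 0.117) against 3.33 and Cd163 at -1.29 (adjusted p = 0.207) against -2.13. The other 12 had a larger one, such as Tac1 at -3.62 (adjusted p = 0.227) against -3.23. Among the 37, Casq2, Mybpc1, Actn2 and Tnnt2 belong to the muscle list itself, so their smaller folds follow by construction. For 25 of the 64, another probe set of the gene was not past the threshold, and for none was one past it in the opposite direction. Probe sets whose names end in _x_at or _s_at, which can take up related transcripts, were read for 9 of the 64: Krt12, Sprr2h, Serpinb6c, Hdc, Tgm2, Elovl7, Casq2, Tnnt2 and Hbb-y.

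Genes known to be induced by glucocorticoids were lower in GR-null skin. Zbtb16, a zinc finger transcription factor, fell by 2.55 ± 0.20 log2 (SE, n = 4 per group, 5.86-fold, adjusted p = 0.00104). Fkbp5, a co-chaperone of steroid receptors, fell by 2.11 ± 0.16 (4.33-fold, adjusted p = 0.000922). The clock gene Per1 fell by 1.27 ± 0.21 (adjusted p = 0.0227), the Krüppel-like factor Klf9 fell by 1.18 ± 0.23 (adjusted p = 0.0372) and the transglutaminase Tgm2 fell by 1.08 ± 0.22 (adjusted p = 0.037). Hif3a, Cebpd and the cyclin-dependent kinase inhibitor Cdkn1c fell too, with log2 fold changes of -0.94, -0.85 and -0.43. Of 33 measured members of the list, 8 fell, 0 rose and 25 were not past the threshold, and 11 fell adjusted over the list alone. At an unadjusted p below 0.05, limma gave 2 higher members. The widely used targets Tsc22d3, Sgk1 and Dusp1, chosen after their values were seen, had log2 fold changes of -0.70, 0.21 and -0.37 with adjusted p of 0.112, 0.601 and 0.158. By camera the list was lower (adjusted p = 0.000458), with adjusted p = 0.678 with an estimated correlation and 0.00836 with the muscle covariate. Zbtb16, Fkbp5 and Hif3a kept their calls without any 1 array, while Per1 lost it in 4 of the 8 fits, Cdkn1c in 6, and Klf9, Tgm2 and Cebpd in 7. Other probe sets of Fkbp5, Klf9, Tgm2, Hif3a and Cebpd were not past the threshold, among them 5 of the 7 of Klf9 and 4 of the 6 of Hif3a.

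Genes of late epidermal differentiation were among the largest falls, beside genes outside that list such as Krt12 and Mrgprb1. Of the small proline-rich proteins, which are crosslinked into the cornified envelope, Sprr1b fell by 4.42 ± 0.49 log2 (SE, adjusted p = 0.00547), Sprr2d fell by 3.34 ± 0.23 (adjusted p = 0.000663) and Sprr2h fell by 2.90 ± 0.34 (adjusted p = 0.00724). Repetin (Rptn) fell by 3.86 ± 0.60 (adjusted p = 0.0174), with wild-type values spread from 6.02 to 9.41 and 2 of its 3 probe sets not past the threshold. Filaggrin (Flg), which bundles keratin filaments in the granular layer, fell by 2.35 ± 0.45 (adjusted p = 0.0339). Of 44 measured members of the cornified envelope and late differentiation list, 9 fell, 0 rose and 35 were not past the threshold. The late cornified envelope gene Lce3f, a member named after its values were seen, had a log2 fold change of 4.77 ± 1.14 (adjusted p = 0.0592). The counts adjusted over the list alone were 12 falls and 1 rise, and at an unadjusted p below 0.05 limma gave 2 higher members. By camera the list was lower (adjusted p = 3.31e-05), with adjusted p = 0.678 with an estimated correlation. Without GR-null 17 it was not past the threshold (adjusted p = 0.101, median log2 fold change -0.11 against -0.34 with all arrays), although 13 members fell and 4 rose in that fit. The mean of the list relative to all arrays was -1.04 log2 in GR-null 17 and between -0.16 and 0.29 in the other GR-null arrays. Sprr1b, Sprr2d and Sprr2h kept their calls without any 1 array. Rptn lost it in 3 of the 8 fits and Flg in 6.

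Single keratins of the suprabasal layers moved in opposite directions, while the others of the list were not past the threshold. Krt77, a type II keratin, rose by 4.52 ± 0.39 log2 (23.0-fold, adjusted p = 0.00171), from 9.07 ± 0.61 (SD, n = 4) to 13.59 ± 0.72. Krt78 fell by 2.18 ± 0.15 (4.52-fold, adjusted p = 0.000663), and Krt80 rose by 1.35 ± 0.29 (adjusted p = 0.0462). The epithelial ETS factor Ehf fell by 1.13 ± 0.23 (adjusted p = 0.0375), with 3 of its 4 probe sets not past the threshold. Of 20 measured members of the suprabasal keratins and calcium-binding proteins list, 2 rose, 2 fell and 16 were not past the threshold, and 2 rose and 4 fell adjusted over the list alone. The list did not differ from other genes (adjusted p = 0.687), with a mean log2 fold change of 0.15, a median of -0.02 and camera's direction downward. With the muscle covariate its adjusted p was 0.0124. Krt77 and Krt78 kept their calls without any 1 array, while Krt80 lost it in 7 of the 8 fits and Ehf in 5. The abundant keratins Krt1 and Krt10, named after their values were seen, had log2 fold changes of -0.15 (95% interval -0.32 to 0.02) and -0.05 (-0.22 to 0.12).

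**Figure D2:**
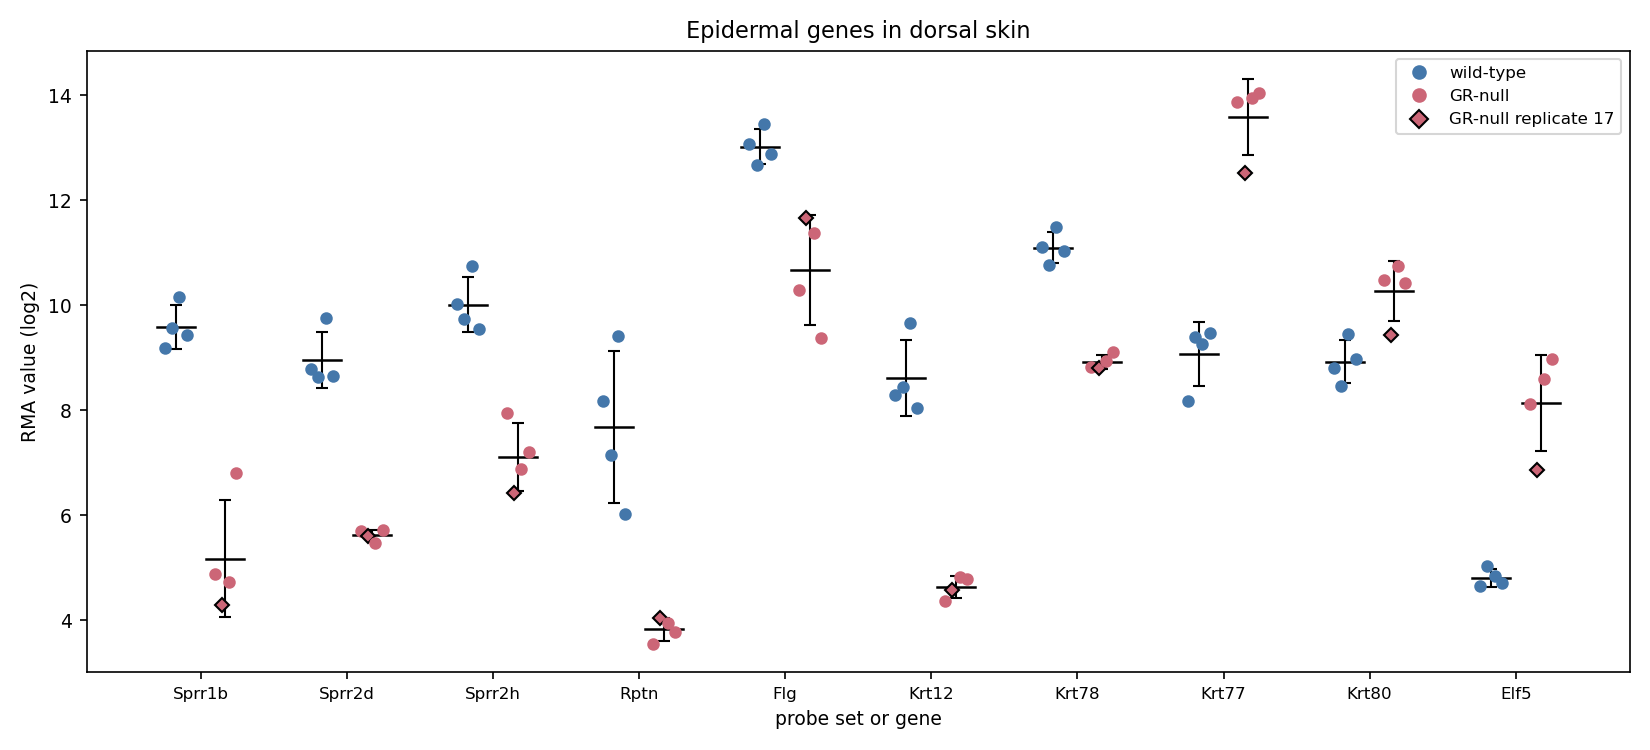
RMA values (log2) on each array for 10 epidermal genes, with 4 wild-type and 4 GR-null points each, the group mean as a horizontal line and the SD as an error bar. GR-null 17, the diamond, had the lowest GR-null values of Krt77 (12.52) and Elf5, but the highest of Flg (11.66).

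In the basal layer, Trp63, a master regulator of stratified epithelia, rose by 0.60 ± 0.12 log2 (adjusted p = 0.0372), the hemidesmosomal collagen gene Col17a1 by 0.59 ± 0.12 (adjusted p = 0.0408) and the laminin gene Lama3 by 0.56 ± 0.11 (adjusted p = 0.0337). Col7a1, the anchoring fibril collagen, fell by 0.70 ± 0.12 (adjusted p = 0.0234). Of 15 measured members of the basal keratinocyte list, 3 rose, 1 fell and 11 were not past the threshold, with the same counts adjusted over the list alone. The list missed the threshold with all arrays (adjusted p = 0.0589) and passed it, upward, without wild-type 6 (0.0202), wild-type 29 (0.0398), GR-null 5 (0.0208) or GR-null 26 (0.0414). With the muscle covariate its adjusted p was 0.00166. All 4 genes lost their calls in 5 or more of the 8 fits without 1 array. Trp63 had 3 of its 4 probe sets not past the threshold, and Lama3 had 1 of its 2.

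By camera the desmosomes and tight junctions list was higher in GR-null skin (adjusted p = 0.0216), with adjusted p = 0.678 with an estimated correlation and 0.357 by fry. Of its 27 measured members, 0 were past the threshold over all genes, while 5 rose adjusted over the list alone, and at an unadjusted p below 0.05 limma gave 8 higher and 1 lower. The members with the smallest p were F11r, a junctional adhesion molecule, at 0.34 ± 0.08 log2 (adjusted p = 0.0535) and the claudin Cldn8 at 0.60 ± 0.14 (adjusted p = 0.0592). The list missed the threshold without wild-type 6 (0.138), without GR-null 25 (0.0542), above the median level (0.114), with the number block (0.0719) and with the muscle covariate (0.78).

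Lipid enzymes showed single changes. Elovl7, a fatty acid elongase, fell by 1.80 ± 0.33 log2 (adjusted p = 0.0308), the fatty acid transporter gene Slc27a4 fell by 0.68 ± 0.13 (adjusted p = 0.0344) and the lipoxygenase Alox12e rose by 0.98 ± 0.12 (adjusted p = 0.00756). The other 36 of 39 measured members of the epidermal barrier lipids list were not past the threshold. Those counts were the same adjusted over the list alone, and the list's adjusted p was 0.45, or 3.03e-05 with the muscle covariate. In cholesterol synthesis, farnesyl diphosphate synthase (Fdps) rose by 1.03 ± 0.15 (2.04-fold, adjusted p = 0.0147) and the sterol oxidase Msmo1 by 0.93 ± 0.16 (adjusted p = 0.0234). Of 21 measured members of the cholesterol synthesis list, 2 rose, 0 fell and 19 were not past the threshold, and 6 rose adjusted over the list alone, while limma gave 2 lower at an unadjusted p below 0.05. The list's adjusted p was 0.12 with all arrays, 0.0492 without wild-type 6, 0.0421 without GR-null 26 and 0.0401 with the muscle covariate. Alox12e kept its call without any 1 array, Fdps lost it without GR-null 25 (adjusted p = 0.0558), and Msmo1, Elovl7 and Slc27a4 lost it in 4, 6 and 6 of the 8 fits. Another probe set of Fdps, of Msmo1 and of Elovl7 was not past the threshold.

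Among epidermal proteases and inhibitors, the serpin Serpinb6c fell by 1.97 ± 0.22 log2 (3.93-fold, adjusted p = 0.00547) and the membrane protease Tmprss13 fell by 1.06 ± 0.17 (adjusted p = 0.018). Of 32 measured members of that list, 2 fell, 0 rose and 30 were not past the threshold, and adjusted over the list alone 2 rose and 6 fell. Its adjusted p was 0.181 with all arrays and 0.0213 without GR-null 25, and 0.000152 with the muscle covariate. Serpinb6c kept its call without any 1 array and Tmprss13 lost it in 5 of the 8 fits. At an unadjusted p below 0.05 limma gave 4 higher members.

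Of the hair shaft and inner root sheath list, 1 of 50 members rose, the forkhead gene Foxq1 by 0.51 ± 0.10 log2 (adjusted p = 0.0394), and the list's adjusted p was 0.16. Of the hair follicle signalling list, 1 of 32 rose, the Wnt target Axin2 by 0.46 ± 0.09 (adjusted p = 0.0405), and the list's adjusted p was 0.302. Of the cell cycle list, 1 of 42 rose, the mitotic kinesin Kif20a by 0.83 ± 0.10 (1.78-fold, adjusted p = 0.0078). The counts were the same for these 3 lists adjusted over the list alone, with 0 falls in each. Unadjusted, limma gave 3, 3 and 2 lower members at p below 0.05. The cell cycle list missed the threshold with all arrays (adjusted p = 0.0626) and passed it, upward, without wild-type 6 (0.00158), GR-null 25 (0.00455) or GR-null 26 (0.0421) with the block for label numbers below 10 (0.0467) and without probe sets prone to cross-hybridisation (0.0102). With the muscle covariate the adjusted p of the 3 lists was 3.03e-05, 0.00145 and 9.30e-05. Kif20a kept its call without any 1 array, while Foxq1 and Axin2 lost it in 6 and 7 of the 8 fits. Foxq1 and Axin2 each had another probe set not past the threshold.

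The cytokine Il18 fell by 2.12 ± 0.26 log2 (4.35-fold, adjusted p = 0.00859) and Cd14, the co-receptor for bacterial lipopolysaccharide, rose by 1.18 ± 0.13 (2.27-fold, adjusted p = 0.0051). These were the members past the threshold among 62 of the list of cytokines, chemokines and inflammatory mediators, with the same counts adjusted over the list alone and a list adjusted p of 0.302. Of 29 measured wound-associated epidermal genes, Sprr1b alone fell, 2 fell adjusted over the list alone, and the list's adjusted p was 0.437. Of 43 collagens and dermal matrix genes, 1 fell, the collagen gene Col5a3 by 1.36 ± 0.28 (adjusted p = 0.041), as it did adjusted over the list alone. That list's adjusted p was 0.34 with all arrays and 0.022 without wild-type 28. Limma gave 3 wound and 4 matrix genes higher at an unadjusted p below 0.05. Il18 and Cd14 kept their calls without any 1 array, and Col5a3 lost it in 7 of the 8 fits. Col5a3 also had another probe set not past the threshold.

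Limma called 0 members over all genes in the adipocyte, circadian clock and steroid receptor lists. Per1 and Fkbp5, which fell, were counted among the glucocorticoid-induced genes instead, and Nr3c1 was in none of these lists. Of 30 adipocyte and lipogenesis genes, 0 were called adjusted over the list alone, 3 had an unadjusted p below 0.05, and the list's adjusted p was 0.419. Its members with the smallest p were the lipase gene Lipe at -0.80 ± 0.19 log2 (adjusted p = 0.0623) and Cebpa at 0.39 ± 0.13 (adjusted p = 0.124). Of 17 circadian clock genes, 5 rose and 1 fell adjusted over the list alone, 7 had an unadjusted p below 0.05, and the list's adjusted p was 0.334. The clock repressors Nr1d1 and Nr1d2 had log2 fold changes of 0.36 ± 0.09 (adjusted p = 0.0633) and 0.69 ± 0.20 (adjusted p = 0.0864). Of 17 steroid receptors and their chaperones, 0 were called adjusted over the list alone, 7 had an unadjusted p below 0.05, and the list's adjusted p was 0.687. The co-chaperone Bag1 stood at -0.43 ± 0.12 (adjusted p = 0.0857) and the coactivator Ncoa3 at -0.50 ± 0.14 (adjusted p = 0.087).

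**Figure D3:**
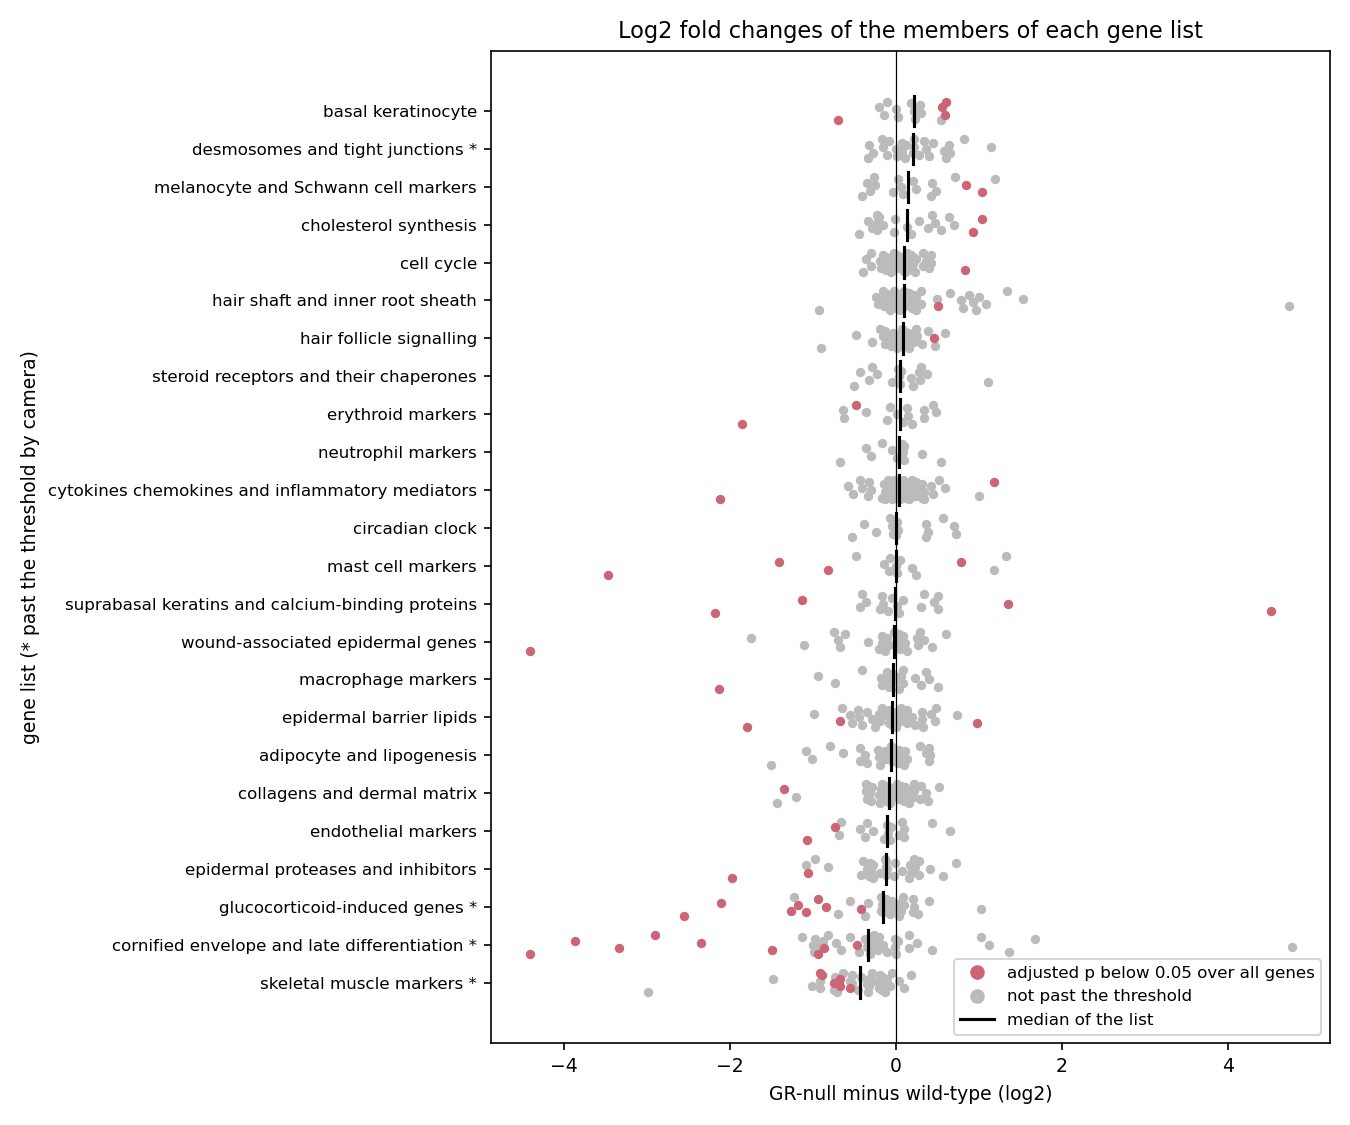
Log2 fold change (GR-null minus wild-type) of every measured member of the 24 gene lists, 1 point per gene at its brightest probe set, coloured where the adjusted p over all genes was below 0.05, with the median of each list as a vertical bar. The 4 lists marked with an asterisk passed the threshold by camera, and their medians were -0.44 for skeletal muscle, -0.34 for cornified envelope, -0.15 for glucocorticoid-induced genes and 0.21 for junctions.

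Transcripts of skeletal muscle were lower in GR-null skin. The cardiac calsequestrin gene Casq2 fell by 0.90 ± 0.14 log2 (SE, n = 4 per group, adjusted p = 0.0179) and the myosin-binding protein gene Mybpc1 fell by 0.92 ± 0.17 (adjusted p = 0.0314). Actn2 fell by 0.75 ± 0.15 (adjusted p = 0.0395) and the troponin gene Tnnt2 fell by 0.68 ± 0.11 (adjusted p = 0.0183). Of 40 measured members of the skeletal muscle markers list, 6 fell, 0 rose and 34 were not past the threshold, and 37 had a log2 fold change below 0. The count adjusted over the list alone was 19 falls, and no member was higher at an unadjusted p below 0.05. By camera the list was lower (adjusted p = 1.87e-10), with adjusted p = 0.678 with an estimated correlation. The mean of the list relative to all arrays lay between 0.19 and 0.35 log2 in wild-type arrays, between -0.57 and -0.31 in GR-null 5, 25 and 26, and at 0.20 in GR-null 17. The median of the list in GR-null 17 was 10.98 log2, against 11.09 to 11.48 in wild-type arrays. In GR-null 17 the 4 named genes lay below all wild-type arrays. The fit that called them included this array, so their selection all but required that. Other probe sets of Mybpc1 and Tnnt2 were not past the threshold, and each of the 4 genes lost its call in 3 or more of the 8 fits without 1 array.

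Mast cell genes were divided. The receptor gene Mrgprb1 fell by 3.47 ± 0.18 log2 (11.1-fold, adjusted p = 0.000189), histidine decarboxylase (Hdc), which makes histamine, fell by 1.41 ± 0.22 (2.66-fold, adjusted p = 0.0167) and the tryptase gene Tpsab1 fell by 0.82 ± 0.15 (adjusted p = 0.0308). The prostaglandin D synthase Hpgds rose by 0.79 ± 0.15 (adjusted p = 0.0314). The other 11 of 15 measured mast cell markers were not past the threshold. The counts adjusted over the list alone were 1 rise and 4 falls, and the list's adjusted p was 0.308. The abundant mast cell transcripts Cpa3, Kit and Cma1, named after their values were seen, had log2 fold changes of -0.00 (95% interval -0.26 to 0.25), 0.02 (-0.23 to 0.26) and 0.24 (0.00 to 0.47). Mrgprb1 kept its call without any 1 array. Hdc lost it without wild-type 28 (adjusted p = 0.0516) and wild-type 29 (0.0598), and 1 of its 2 probe sets was not past the threshold. Tpsab1 and Hpgds lost theirs in 6 and 7 of the 8 fits.

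Vascular, blood and pigment cell markers changed in few members. Von Willebrand factor (Vwf) fell by 1.07 ± 0.23 log2 (adjusted p = 0.0466) and the lymphatic receptor gene Lyve1 fell by 0.73 ± 0.11 (adjusted p = 0.0176), while 17 of 19 endothelial markers were not past the threshold. There were 4 endothelial falls adjusted over the list alone. The list missed the threshold with all arrays (adjusted p = 0.0506) and passed it, downward, without wild-type 28 (0.00196), GR-null 17 (0.0452), GR-null 25 (0.0309) or GR-null 26 (0.0421), and in 4 other settings with adjusted p from 0.0354 to 0.043. The scavenger receptor Cd163 fell by 2.13 ± 0.29 (4.39-fold, adjusted p = 0.0112), alone among 20 macrophage markers, with 2 falls adjusted over the list alone and a list adjusted p of 0.586. Of 16 erythroid markers, the embryonic globin Hbb-y fell by 1.86 ± 0.32 (adjusted p = 0.0241) and the spectrin gene Sptb fell by 0.48 ± 0.09 (adjusted p = 0.0304). The counts were the same adjusted over the list alone, and the erythroid list's adjusted p was 0.765, with a median log2 fold change of 0.05, a mean of -0.13 and camera's direction downward. Of 12 neutrophil markers, limma called 0 over all genes or over the list alone, 2 had an unadjusted p below 0.05, and the list's adjusted p was 0.765 (0.047 with the muscle covariate), with a median of 0.04, a mean of -0.03 and camera's direction upward. Prtn3 and Mmp8 stood at 0.31 ± 0.09 (adjusted p = 0.103) and -0.31 ± 0.11 (adjusted p = 0.161). Cd163 kept its call without any 1 array, while Lyve1, Hbb-y, Sptb and Vwf lost theirs in 3, 5, 6 and 7 of the 8 fits. Hbb-y and Sptb each had another probe set not past the threshold.

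Of the pigment cell genes, tyrosinase (Tyr), the rate-limiting enzyme of melanin synthesis, rose by 1.04 ± 0.12 log2 (2.05-fold, adjusted p = 0.00688) and the melanosome protein gene Pmel by 0.85 ± 0.11 (1.80-fold, adjusted p = 0.0103), and both kept their calls without any 1 array. Of 18 melanocyte and Schwann cell markers, 2 rose, 0 fell and 16 were not past the threshold, and adjusted over the list alone 5 rose and 2 fell. At an unadjusted p below 0.05 limma gave 4 lower. The list's adjusted p was 0.0992 with all arrays and 0.0414 without GR-null 26, and 0.000159 with the muscle covariate. Tyr had another probe set not past the threshold.

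Outside the lists, the largest rises included epithelial and signalling genes. Elf5, an epithelial ETS transcription factor, rose by 3.33 ± 0.38 log2 (10.1-fold, adjusted p = 0.00617), from 4.80 ± 0.17 (SD, n = 4) to 8.14 ± 0.92. The fibroblast growth factor Fgf1 rose by 1.96 ± 0.31 (3.89-fold, adjusted p = 0.0183) at all 3 of its probe sets, and its gene lies 5 genes from Nr3c1. Among the 78 measured genes within 100 positions of Nr3c1 it was the 1 past the threshold, against 537 of 18115 elsewhere (odds ratio 0.425, 95% interval 0.0106 to 2.45, two-sided Fisher's exact p = 0.731). The chitinase-like Chil1, the chloride channel regulator Clca3a2, Sectm1a and Eaf2 rose by 1.77, 1.73, 1.70 and 1.62. The orphan receptor Gpr37, the cytochrome P450 genes Cyp2f2 and Cyp17a1, and the G-protein regulator Rgs18 rose by 1.56, 1.38, 1.28 and 1.22. Elf5, Clca3a2, Eaf2 and Rgs18 kept their calls without any 1 array, while Chil1 lost its call in 4 of the 8 fits, Fgf1 and Sectm1a in 5, and Gpr37, Cyp2f2 and Cyp17a1 in 7. Another probe set of Elf5 was not past the threshold.

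Large falls outside the lists were in genes of several kinds. Krt12, a keratin known from the corneal epithelium, fell by 3.97 ± 0.31 log2 (15.7-fold, adjusted p = 0.00111) at both of its probe sets. Tac1, the precursor of the neuropeptide substance P, fell by 3.23 ± 0.55 (9.38-fold, adjusted p = 0.0234). The carboxylesterase Ces2f fell by 2.94 ± 0.30 (adjusted p = 0.0044), the flavin monooxygenase Fmo2 fell by 2.57 ± 0.53 (adjusted p = 0.0408) and Tmigd1 fell by 2.23 ± 0.31 (adjusted p = 0.014). Krt12 and Ces2f kept their calls without any 1 array. Tac1, Tmigd1 and Fmo2 lost theirs in 4, 2 and 7 of the 8 fits, and other probe sets of Tac1, Ces2f and Fmo2 were not past the threshold.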

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

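All the tests of explanations in this part were chosen after the results were seen, and the bound on unadjusted counts in the muscle test and the condition on lists outside the epidermis were added after the first outcome of their tests. The tests of a wrong genotype label and of fewer mast cells replaced earlier ones on genes picked by their values, after the outcome of those was seen. Of 208 groups of 4 arrays examined for 1 value far from the other 3, 10 stood out by Dixon's criterion. Chance gives about 1 in 20 groups, which is about as many as stood out.

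GR-null 17 held 3 of them. Its Krt77 value was 12.52 log2 against 13.87 to 14.04 in the other GR-null arrays, its Eaf2 value 6.43 against 7.35 to 7.49, and its Prtn3 value 6.40 against 6.06 to 6.11. In wild-type 6 the brightest Nr3c1 probe set read 10.32 against 10.24 in the other 3, a gap of little size, and the mean of the cell cycle list was 0.115 log2 above the mean of all arrays against -0.10 to -0.08. In wild-type 28 Sprr2d read 9.76 against 8.62 to 8.78, and the mean of the wound-associated list was 0.359 against 0.08. Krt77 read 8.17 in wild-type 4 against 9.26 to 9.47, Fgf1 5.23 in wild-type 29 against 5.64 to 5.67, and Rgs18 8.61 in GR-null 25 against 8.50 to 8.51.

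GR-null 17 stood apart over many genes, with a root mean square deviation from the rest of its group of 0.378 log2, against 0.20 to 0.301 on the other 7 arrays. A wrong genotype label is argued against by Nr3c1, 9.24 log2 against 10.24 to 10.32 in wild-type. Of the 11 glucocorticoid-induced genes lower in the fit without GR-null 17, 9 lay below all wild-type arrays in it. Chance would allow a further wild-type array 5 if genes were independent and not picked on these arrays. The 11 genes were picked against the same wild-type arrays, so their count does not decide on the label. GR-null 17 shared high Xist with wild-type 6, but across 18190 genes, which are not independent replicates, the deviations of these arrays from their groups had r = -0.162. No common effect of sex over many genes is therefore seen. Each deviation comes from 1 array and mixes sex with all else particular to it, so an effect on fewer genes could be missed. A less advanced epidermis and a different mix of tissues cannot be told apart, since the mean over the cornified envelope list, -4.44 SDs from the other 3 GR-null arrays, had prompted the test. Of its 44 members, 38 read lowest in GR-null 17 among the GR-null arrays and 3 highest, Flg among them (11.66 log2). The other epidermal lists ran from -4.66 SDs for barrier lipids to 2.06 for cholesterol synthesis, with basal keratinocytes at 0.42. Of 16 lists outside the epidermis, 7 also lay over 3 SDs away, among them hair shaft (0.57 log2 against -0.05 to 0.07), adipocyte (0.46 against -0.39 to -0.21) and neutrophil (0.77 against -0.46 to -0.18). Each SD came from 3 arrays, so these distances are imprecise, and how many lists chance would give was not worked out. RNA quality, litter and a sex effect particular to the null genotype stay open as untested.

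Skeletal muscle transcripts were lower in GR-null skin, with a mixed picture in GR-null 17, whose list mean (10.68 log2) reached the wild-type level while its list median (10.98) lay below the wild-type 11.09 to 11.48. If the samples merely held less muscle, members would shift about alike, apart from very bright or dim ones, whose changes RMA compresses. After subtracting the list median of each array, limma called 0 of the 40 members over the list (smallest adjusted p 0.154). At an unadjusted p below 0.05 limma gave 9, of which 5 were relatively higher and 4 relatively lower. Chance would allow 5 if the members were independent. They share the arrays and the subtracted median, so 9 need not exceed chance. A smaller share of muscle as the whole cause and a change within the muscle cells therefore cannot be told apart with these arrays. Whether the dissection or the embryos differed stays open, since the labels do not describe the depth of the skin sample.

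Of the mast cell genes, some fell, Mrgprb1 and Hdc among them. Fewer mast cells in the samples could lower both, but would lower the other mast cell transcripts too, about alike except where RMA compresses changes. Of the 11 list members other than Hdc above the median level in wild-type arrays, 9 had a 95% interval above that of Hdc (-1.90 to -0.93 log2), among them Cpa3 (-0.26 to 0.25) and Cma1 (0.00 to 0.47), which were brightest. Hdc was the reference because it fell, so that choice in part set the count of 9. The intervals of Cpa3 and Cma1 do not depend on it and argue against fewer mast cells as the cause of the fall of Hdc. RMA can understate changes of bright transcripts such as these, and some members, such as Kit and Gata2, are known from other cell types too. A change of expression within mast cells remains as a hypothesis, and expression of Hdc in other cell types was not tested.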

How the results depend on the processing

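The muscle covariate and the variance prior from 1 probe set per gene were chosen after seeing the data. No paired analysis was possible because the groups share no label numbers. Of the 35 splits of the 8 arrays into 4 and 4, 1, the real one, gave as many as 539 genes, and the highest other gave 1 gene. The smallest share this test can give is 1 in 35, and the other splits mix the genotypes, which raises the spread within groups. The splits therefore argue against chance for the count but cannot exclude it. Within 1.5 times the 539 genes were further quantile normalization (553), the trended robust prior (476), the Y-linked covariate (590), the number block (460), no _x_at or _s_at probe sets (539), no neighbours of Nr3c1 (538) and the prior from 1 probe set per gene (673). None of the named genes past the threshold changed direction in an alternative that read it. Apart from Krt80, their groups did not overlap, so leaving out an array, array weights or another variance prior could not have reversed them. All 64 were read in each alternative but 3, which read 54 (above the median level), 60 (no _x_at or _s_at) and 63 (no neighbours). The brightest Nr3c1 probe set ranged from -0.90 to -0.77 without 1 array and stood at -0.91 with the muscle covariate, where its call ended.

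Leaving out 1 array gave 79 to 1640 genes (19 to 692 higher, 60 to 948 lower), 125 to 4866 probe sets (37 to 2650 higher, 88 to 2216 lower) and 4 to 9 lists, against 4 with all arrays. The smallest gene and probe set counts came without GR-null 25 and the largest without GR-null 17, while 9 lists passed without GR-null 26. Fewer arrays give less power by construction, yet both counts rose without GR-null 17, and without wild-type 6 the probe set count rose to 2104 while the gene count was 321. Array quality weights, which gave GR-null 17 the lowest weight (0.470), gave 1944 genes (882 higher, 1062 lower) and 5831 probe sets (3316 and 2515). The muscle covariate gave 75 genes (45 and 30), 25 probe sets (10 and 15) and 12 lists. It follows genotype in part, so its fit has less power for genotype. The list mean was 9.91 to 10.17 log2 in GR-null 5, 25 and 26, but 10.68 in GR-null 17, against 10.67 to 10.83 in wild-type. The genotype effect at an equal muscle level therefore leans on GR-null 17, which stood apart over many genes. Calls and lists that change with this covariate cannot be read as an adjustment for muscle alone. Of the 49 named genes whose calls it ended, 37 had smaller folds and 12 larger ones, while of the 15 kept, 4 had smaller and 11 larger ones. Among the 37 are Casq2, Mybpc1, Actn2 and Tnnt2, which are part of the covariate itself, so smaller folds follow for them by construction. A threshold of 0.01 gave 46 genes (13 and 33) and 74 probe sets (22 and 52). At least 1.5-fold left 297 genes (101 higher) and 1075 probe sets (611 and 464). Probe sets above the median level gave 829 genes (419 higher), as fewer were tested. The mean of all probe sets gave 884 genes (525 higher), 365 of them among the 539. The number block gave 164 higher genes. Camera with an estimated correlation called 0 lists (1 at an unadjusted p below 0.05) and fry called 1, glucocorticoid-induced genes (adjusted p = 0.0327; 3 lists unadjusted). Beyond these constructions the cause was not tested. No signal over background was used, so dim probe sets limit what can be seen.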

Other observations

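The genes in this part were chosen after their values were seen, and no test of an explanation was made for them.

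Genes outside the lists that fell in GR-null skin included the following, which were not tested as a group. The transcriptional repressor Gfi1 fell by 1.88 ± 0.13 log2 (SE, n = 4 per group, 3.69-fold, adjusted p = 0.000663). Csf2rb, the beta chain common to several cytokine receptors, and Csf2rb2, a beta chain of the interleukin-3 receptor, fell too, with log2 fold changes of -1.66 ± 0.20 (adjusted p = 0.00721) and -2.19 ± 0.28 (adjusted p = 0.0107). Gpr65, a proton-sensing receptor, fell by 1.71 ± 0.27 (adjusted p = 0.0183), Gcsam fell by 1.82 ± 0.21 (adjusted p = 0.00611) and Ctla2a fell by 1.74 ± 0.25 (adjusted p = 0.0141). In the other direction, Clec12b rose by 1.04 ± 0.19 (adjusted p = 0.0306) and the tetraspanin Cd9 by 0.99 ± 0.18 (adjusted p = 0.0303). Of the alcohol dehydrogenases, Adh1, which oxidises retinol, fell by 1.55 ± 0.15 (2.93-fold, adjusted p = 0.00309) and Adh6b fell by 2.12 ± 0.20 (4.33-fold, adjusted p = 0.00317). Bleomycin hydrolase (Blmh), which degrades filaggrin peptides, fell by 1.49 ± 0.16 (2.80-fold, adjusted p = 0.00492).

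The GR-null arrays were split in some genes not past the threshold, such as Lce3f and Krtap13. Lce3f read 12.74, 12.27 and 13.63 log2 in GR-null 5, 25 and 26 but 7.42 in GR-null 17, against 6.51 to 6.96 in wild-type (log2 fold change 4.77 ± 1.14, adjusted p = 0.0592). The hair shaft gene Krtap13 read 8.71, 8.33 and 13.34 in GR-null 5, 25 and 26 and 3.74 in GR-null 17, against 3.68 to 3.88 in wild-type (adjusted p = 0.135). Gaps above 2 log2 within both genotypes occurred in 9 genes, 4 of them sex-linked. One of the others, the mast cell protease Mcpt2, read 10.21, 5.68, 11.45 and 6.03 in wild-type 4, 6, 28 and 29, and 6.18, 12.63, 12.83 and 6.47 in GR-null 5, 17, 25 and 26. The adipocyte hormone gene Adipoq read 11.40, 5.66, 4.62 and 10.56 in the same wild-type order, and 9.08, 11.72, 6.85 and 4.36 in GR-null arrays. The remaining 3 were Sprr1a, Snhg14 and AI506816.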
